A study of Mus musculus with 20 samples.

How the data were processed

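RNA of 20 samples was measured on Affymetrix Mouse Gene 1.0 ST arrays: mouse splenic B cells of 2 genotypes (wild type and TAK1-deleted, the latter carrying floxed Map3k7 alleles with the B lineage deleter mb-1) at 0, 1, 3, 6 and 24 h of anti-IgM at 10 µg/ml, with 2 arrays per group. Per the labels, total RNA was extracted with a column kit and biotin-labelled, and the mice were 8 to 12 weeks old and of mixed sex. The authors made the deposited values, which are on the log2 scale, with RMA and Affymetrix Expression Console 1.0, per the submitters' processing notes. The genome build and annotation behind the probe sets are not given in the sources used here. Raw scans were not used here.

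The table holds 35556 probe sets with values of 3.64 to 14.68, no missing value and array medians of 7.37 to 7.52, and was used as deposited. The annotation table for the platform lists 23410 of the probe sets. Of these 21789 carry 1 gene symbol and 1621 several, and 12146 probe sets of the value table are not listed. Of the probe sets with 1 symbol 21698 were matched to the gene table by gene ID, which changed 0 symbols. Probe sets were kept when they reached the median of all values (7.45) in at least 2 arrays, which 20326 did. Of these 7191 had several symbols or none and were left out. For a gene with several probe sets (999 genes) the one with the highest mean over all arrays was used, which left 11968 genes. RMA values carry a background that is not subtracted to 0 and detection p-values were not used here, so folds against groups in which a gene is dim can be understated.

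Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend) on all 20 arrays at once, with 10 residual degrees of freedom and a prior of 5.47. The 17 contrasts were each time against 0 h within a genotype (8), TAK1-deleted against wild type at each time (5) and the difference between the genotypes in the change from 0 h (4, called the response). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its contrast, two-sided. The words rose, fell, higher and lower are used of genes that were called, and of a gene list by its test. Where values without a call are described, the text says so. The contrasts, lists, filter, alternatives and the rule for named genes were set before the data were examined.

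In each contrast the rule named the 3 called genes with the largest rise and the 3 with the largest fall among those whose groups did not overlap (called alone for the response). It also named up to 4 called members of each gene list with the largest change, and 15 genes in every contrast: Map3k7, Nfkbia, Tnfaip3, Rel, Myc, Egr1, Fos, Ccnd2, Cd69, Cd83, Cd86, Bcl2l1, Irf4, Ighm and Cd79a. Of the genes it named, the text gives mainly those whose call held with each array of the contrast left out in turn, a choice made after the values were seen.

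Gene lists numbered 34 with 601 symbols, of which 545 had a probe set. They cover NF-κB targets, immediate early genes, components of the NF-κB and B cell receptor pathways, activation surface markers, chemokines and cytokines, quiescence genes, ribosome biogenesis, G1/S, G2/M, G1 cyclins and CDK regulators, anti-apoptotic and pro-apoptotic genes, glycolysis, amino acid transport and serine or one-carbon metabolism, cholesterol biosynthesis, the unfolded protein response, heat shock, the interferon response, antigen presentation, p53 targets, and class switch and germinal centre genes. Cell marker lists cover pan B, follicular, marginal zone, transitional or immature, B-1 and plasma cells, T cells, NK cells, monocytes or macrophages, neutrophils, dendritic cells, erythroid cells and platelets or megakaryocytes. Each list was tested in each contrast with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over all 526 tests; the response was tested for the lists that are not cell markers. Of these 301 were called. With a correlation estimated for each list 18 were called, all among the 301; they are heat shock at 1 h in both genotypes, monocyte or macrophage markers (wild type at 6 and 24 h, TAK1-deleted at 1, 3 and 6 h, and between genotypes at 24 h), erythroid and NK cell markers between genotypes at 0, 1, 3 and 6 h, neutrophil markers between genotypes at 24 h and B-1 cell markers between genotypes at 3 h. The tool fry, which asks whether a list's genes move one way and does not compare them with other genes, called 276. The correlation was estimated without the replicate block, so deviations shared by arrays of the same number can enter it. Calls said to hold or not to hold with an estimated correlation refer to that estimate. A test with both the replicate block and an estimated correlation was added after the values were seen. In no called list did the median, the mean and the test differ in sign. Counts of members are given over all genes tested and adjusted over the list alone.

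The labels number the replicates 1 and 2 and say nothing more of them. Whether the numbers pair the samples was checked on the deviations of the arrays from their group means: in the 45 pairs of groups the correlation of these deviations across genes was 0.191 to 0.769 (median 0.535). The 75th percentile of the arrays averaged 9.41 in replicates numbered 1 and 9.28 in those numbered 2. The numbers therefore pair the samples, and the replicate number was added as a block in an alternative planned beforehand.

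Alternatives were no filter and a stricter filter (9.35, the 75th percentile, which kept 7101 genes), the mean over a gene's probe sets, every probe set tested, quantile normalization again, centring on the median of the tested genes, no intensity trend, a fit of each contrast's arrays alone, a change of at least 2-fold, an adjusted p below 0.01, the block, and leaving out each array of a contrast in turn, where the lone array of a group is assumed to vary like the others. On simulated data, drawn from normal noise with the residual spread of each gene around the wild type means, independent between arrays and so without the pairing described above, and with 100 genes changed at each of the folds 1.5 and 2, the same fit recovered 87% of the 2-fold and 40% of the 1.5-fold changes between genotypes at 1 h, 89% and 38% at 24 h, and 44% and 7% for the response at 1 h. It made 4, 7 and 4 false calls among 11968 genes. The share of the wild type response kept was computed on genes chosen in wild type replicate 1 and read in the other arrays, so that the wild type change is not read from the arrays that chose the genes. Since the numbers pair the samples, TAK1-deleted replicate 1 shares deviations with the choosing arrays and is not independent of the choice, and the SD of 2 replicates leaves out the spread from that choice. Splits of the samples into other groups and tests for outlying samples were not made, since groups hold 2 arrays. Figures were drawn with matplotlib 3.10.9.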

Results

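Gene expression was measured on 20 arrays of total RNA from splenic B cells of C57BL/6 mice, in 10 groups of 2 arrays. The cells came from wild type mice or from mice whose B lineage lacks TAK1, the kinase encoded by Map3k7 that passes signals from the B cell receptor to the IκB kinase complex and to MAP kinases. The cells were purified by depletion of CD43-bearing cells with magnetic beads and taken without stimulation (0 h) or after 1, 3, 6 or 24 h with anti-IgM, an antibody that cross-links the B cell receptor, at 10 µg/ml. The labels do not say whether the 0 h cells were kept in culture, so changes from 0 h may include those of culture. Values across 11968 tested genes correlated between the 2 replicates of a group with r of 0.979 to 0.994, computed across genes, which are not independent replicates. Changes are log2 fold changes ± standard error from limma, with 2 arrays in each group and an adjusted p for each gene. The median standard error was 0.161 for a difference between groups, and the number of arrays limits the precision. The labels do not say whether the replicates are separate mice or cultures, so the p-values measure the spread between these samples, which may be technical.

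Map3k7 itself was detected at a similar level in every array. Its single probe set (10503680) read 10.16 to 10.71 in the wild type samples and 10.4 to 10.76 in the TAK1-deleted samples, on the log2 scale. The difference between TAK1-deleted and wild type samples was 0.26 ± 0.14 at 0 h (adjusted p = 0.721) and 0.30 ± 0.14 at 1 h (adjusted p = 0.369), and with the replicate as a block the value at 1 h passed the test (adjusted p = 0.0209). At 3, 6 and 24 h it was 0.07, 0.06 and 0.10 (adjusted p = 1, 0.92 and 0.754). The labels do not say which part of the gene was deleted and the positions of the probes were not analysed here, so these values do not check the genotypes.

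The first question is how wild type B cells responded to anti-IgM. After 1 h, transcription factor and feedback genes of the immediate early class rose steeply. Of 28 tested immediate early genes 25 rose and 1 fell (25 and 2 adjusted over the list alone), among them the nuclear receptor genes Nr4a2 (5.58 ± 0.21, adjusted p = 3.39e-11) and Nr4a3 (5.14 ± 0.16) and the AP-1 gene Fosb (5.12 ± 0.17). Of 32 tested NF-κB targets 20 rose and 2 fell (23 and 4 adjusted over the list alone). They included the chemokine genes Ccl3 (3.76 ± 0.21) and Ccl4 (3.73 ± 0.16) and Tnfaip3, which encodes the NF-κB inhibitor A20 (2.68 ± 0.16). Myc rose by 2.30 and Irf4 by 2.10. All 10 heat shock genes rose (10 adjusted over the list alone), led by Hspb1 (5.97 ± 0.35) and Hspa1a (3.90 ± 0.21). Of 15 activation surface markers 9 rose and 1 fell (10 and 1 adjusted over the list alone), with Cd69 at 2.46 ± 0.15 and Cd83 at 1.81 ± 0.10. Transcripts of other cells fell at the same time: 14 of 17 monocyte or macrophage markers fell and 1 rose (15 and 1 adjusted over the list alone), and the iron exporter gene Slc40a1 fell by 2.60. In camera tests against the other genes the adjusted p was 8.98e-29 for immediate early genes, 1.89e-13 for NF-κB targets, 4.78e-17 for heat shock, 1.27e-06 for surface markers and 1.12e-10 for monocyte or macrophage markers. The adjusted p with an estimated correlation was 0.154, 0.182, 0.0398, 0.318 and 0.0662, in the same order, so that the heat shock call alone of these held. In all 2930 genes changed at 1 h, 1271 up and 1659 down. Without wild type 0 h replicate 1 the count was 1853, and with the replicate as a block it was 5172.

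At 3 h the genes of ribosome assembly rose together. All 30 tested ribosome biogenesis genes rose (30 adjusted over the list alone), among them Rrp9 (2.12 ± 0.24), Nhp2 (2.07 ± 0.21) and Nop58 (2.03 ± 0.15). Of 17 genes of amino acid transport and serine or one-carbon metabolism 14 rose (14 adjusted over the list alone), with the cystine transporter gene Slc7a11 at 2.73 ± 0.19 and the leucine transporter gene Slc7a5 at 2.56 ± 0.10. Il2ra, the gene of an interleukin 2 receptor chain, rose by 3.69 ± 0.25, and Bcl2l1, which encodes the survival protein Bcl-xL, by 2.45 ± 0.13. The falls were led by Serpinb10 (-4.62), Slc40a1 (-4.30) and the complement gene C1qc (-4.21), and 15 of 17 monocyte or macrophage markers fell (15, with 1 higher, adjusted over the list alone). The adjusted p was 1.81e-18 for ribosome biogenesis, 4.93e-08 for amino acid genes and 2.15e-11 for monocyte or macrophage markers. None of these 3 calls held, with adjusted p = 0.182, 0.318 and 0.0554 with an estimated correlation. In all 2497 genes rose and 2780 fell.

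At 6 h interferon-induced and sterol synthesis genes were up. Of 23 interferon response genes 19 rose and 1 fell (19 and 1 adjusted over the list alone), among them Ifit1 (2.38 ± 0.15), Rsad2 (2.29 ± 0.20) and Usp18 (2.29 ± 0.15). At 1 h 9 of the same 23 had fallen and 2 had risen. Of 18 cholesterol biosynthesis genes 16 rose (16 adjusted over the list alone), with Idi1 at 2.63 ± 0.22 and the squalene epoxidase gene Sqle at 2.46 ± 0.15. Among 19 components of the B cell receptor and NF-κB pathways 10 fell and 3 rose (10 and 3 adjusted over the list alone), and the kinase gene Syk fell by 2.04 ± 0.15. Ighm and Cd79a, which encode parts of the receptor, fell by 1.10 and 1.07. Of 17 monocyte or macrophage markers 14 fell (15 adjusted over the list alone), with C1qb at -5.02 ± 0.14, and the dendritic cell gene Cd209a fell by 4.97 ± 0.20. The adjusted p was 3.9e-08 for the interferon list, 1.91e-09 for cholesterol biosynthesis, 0.0113 for pathway components and 2.12e-13 for monocyte or macrophage markers, and with an estimated correlation the adjusted p = 0.384, 0.201, 0.562 and 0.0412. In all 2889 genes rose and 2280 fell.

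By 24 h the wild type cells carried high levels of DNA replication and mitosis transcripts. Of 31 G1/S and DNA replication genes 30 rose and 1 fell (30 and 1 adjusted over the list alone), among them Orc1 (2.86 ± 0.14), Chek1 (2.82 ± 0.33) and Uhrf1 (2.38 ± 0.14). Of 25 G2/M and mitosis genes 24 rose (25 adjusted over the list alone), with the mitotic kinase gene Cdk1 at 2.01 ± 0.19. Of 22 quiescence genes 17 fell (18 adjusted over the list alone), including the lymphocyte egress receptor gene S1pr1 (-2.98 ± 0.16), Bcl6 (-2.78 ± 0.19) and Txnip (-2.34 ± 0.14). Ccnd2 rose by 1.41 ± 0.17 while Ccnd1 fell by 2.67 ± 0.16. All 13 pan B cell markers fell (13 adjusted over the list alone), with Cd22 at -1.86 ± 0.20, and so did all 4 follicular B cell markers (4 adjusted over the list alone) and 7 of 9 marginal zone B cell markers (7 adjusted over the list alone; Cr2 -3.36 ± 0.15). The markers of other cells fell as well: 14 of 14 for T cells, 10 of 10 for NK cells, 16 of 17 for monocytes or macrophages, 13 of 14 for neutrophils and 7 of 9 for dendritic cells, with the same numbers adjusted over the list alone. The adjusted p was 8.79e-18 for G1/S, 1.53e-10 for G2/M, 3.05e-09 for quiescence and 5.92e-07 for pan B cell markers. With an estimated correlation the adjusted p = 0.182, 0.342, 0.351 and 0.351. It was 8.65e-05 for follicular, 5.84e-05 for marginal zone, 2.38e-09 for T cell, 2.63e-09 for NK cell, 3.39e-11 for neutrophil and 4.24e-06 for dendritic cell markers, and with an estimated correlation the adjusted p = 0.24, 0.284, 0.284, 0.094, 0.0715 and 0.236. The call for monocyte or macrophage markers (adjusted p = 2.69e-12) held with an estimated correlation (adjusted p = 0.0457). In all 2820 genes rose and 2418 fell.

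The same comparison was made within the TAK1-deleted samples. After 1 h, 25 of 28 immediate early genes rose and 1 fell (25 and 1 adjusted over the list alone), and all 10 heat shock genes rose (10 adjusted over the list alone). Plk2 (5.73 ± 0.20), Nr4a2 (5.59 ± 0.21) and Nr4a3 (5.37 ± 0.16) led the rises. Of the 32 NF-κB targets 15 rose and 4 fell (15 and 4 adjusted over the list alone). Bcl2l1, at 1.23 ± 0.13 in wild type, measured 0.05 ± 0.13 here and was not called. Ribosome biogenesis genes rose in full at 3 h and at 6 h (30 of 30 each, 30 adjusted over the list alone), and 16 of 18 cholesterol biosynthesis genes rose at 6 h (17 adjusted over the list alone). G2/M genes fell in 24 of 25 cases at 6 h (24 adjusted over the list alone), with Ccna2 at -1.82 ± 0.20 and Mki67 at -1.71 ± 0.13. Erythroid markers fell at the same time, 9 of 9 (9 adjusted over the list alone). At 24 h 21 of 31 G1/S genes rose and 1 fell (22 and 1 adjusted over the list alone), with Uhrf1 at 1.40 ± 0.14, and 1 of 25 G2/M genes rose and 6 fell (1 and 6 adjusted over the list alone). Erythroid markers fell in 9 of 9 cases at 24 h (9 adjusted over the list alone; Car1 -6.31 ± 0.21), while Gpnmb (4.02 ± 0.16), Pdcd1 (3.97) and the MAP kinase phosphatase gene Dusp4 (3.65 ± 0.19) rose most. The erythroid fall was not particular to this genotype, since Car1 fell by 5.33 ± 0.21 in wild type at 24 h. In wild type the erythroid list was also called at 6 and 24 h, in calls lost on leaving out 1 array or another.

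For the lists named in the TAK1-deleted samples the adjusted p at 1 h was 5.6e-33 for immediate early genes, 2.54e-18 for heat shock and 4.16e-07 for NF-κB targets. For the same lists the adjusted p = 0.115, 0.035 and 0.351 with an estimated correlation. Ribosome biogenesis gave 7.14e-18 at 3 h and 1.19e-15 at 6 h, and cholesterol biosynthesis 3.1e-12 at 6 h, with adjusted p = 0.182, 0.205 and 0.172 with an estimated correlation. For G2/M genes the adjusted p was 4.68e-11 at 6 h and 0.00676 at 24 h, and with an estimated correlation the adjusted p = 0.326 and 0.661. The G2/M call at 24 h was lost without the TAK1-deleted 0 h replicate 1 (adjusted p = 0.0644). G1/S genes at 24 h gave 1.48e-07, and erythroid markers 9.72e-07 at 6 h and 1.26e-12 at 24 h. In the same order the adjusted p = 0.399, 0.197 and 0.0855 with an estimated correlation. Monocyte or macrophage markers fell in 13, 15, 16 and 8 of 17 cases at 1, 3, 6 and 24 h (14, 16, 16 and 9 adjusted over the list alone). Their calls at 1, 3 and 6 h held with an estimated correlation (adjusted p = 0.0457, 0.0412 and 0.0294), and that at 24 h did not (adjusted p = 0.0016, and adjusted p = 0.318 with an estimated correlation). In all 2304 genes changed at 1 h (1089 up and 1215 down), 4985 at 3 h (2340 and 2645), 4289 at 6 h (2218 and 2071) and 3301 at 24 h (1785 and 1516). The count at 1 h was 1496 without the TAK1-deleted 0 h replicate 1 and 4340 with the replicate as a block. At 24 h it was 2069 without the TAK1-deleted 24 h replicate 1 and 5340 with the block.

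**Figure D1:**
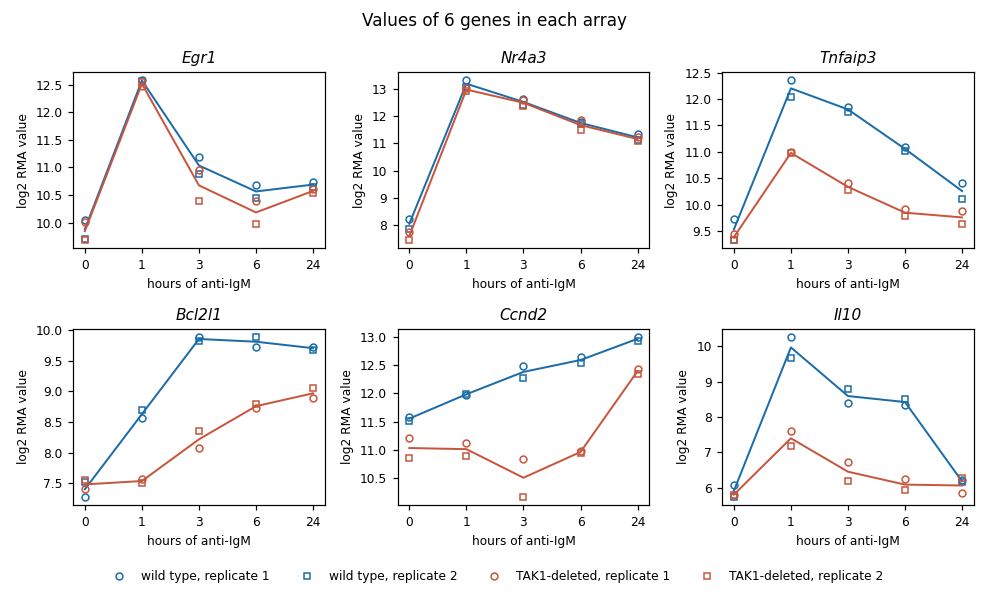
Log2 RMA value of 6 genes against hours of anti-IgM (time points drawn at even spacing); circles and squares are the single arrays of replicates 1 and 2, lines join the means of the 2 arrays, blue is wild type and red is TAK1-deleted. Egr1 and Nr4a3 had no called difference between genotypes (with the replicate as a block Nr4a3 at 0 h and Egr1 at 6 h passed, adjusted p = 0.00168 and 0.046), while Tnfaip3, Bcl2l1, Ccnd2 and Il10 were lower in the TAK1-deleted samples at 1, 3 and 6 h.

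How much of the wild type rise was kept without TAK1 was measured on genes chosen in wild type replicate 1 and read in the other arrays. Genes at least 2-fold higher in that replicate rose in wild type replicate 2 by a median of 1.39, 1.40, 1.46 and 1.18 at 1, 3, 6 and 24 h (508, 732, 772 and 920 genes). The TAK1-deleted samples reached 90.8% ± 1.80 of this at 1 h and 86.6% ± 2.54 at 3 h (SD, n = 2). At 6 h they reached 69.2% ± 6.38 and at 24 h 53.6% ± 1.56. With genes chosen in wild type replicate 2 the shares at 1 and 3 h were 83.5% and 90.8%, so their order is not firm. No test was made, since genes are not replicates. Each share is a change from the genotype's own 0 h, where cell cycle genes were already higher in the TAK1-deleted samples (given below). For any such genes among those chosen, that start lowers the share, and sex was not matched between the genotypes.

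Between genotypes, the unstimulated samples already differed. Erythroid transcripts were higher in the TAK1-deleted samples: all 9 tested erythroid markers rose (9 adjusted over the list alone), including the band 3 gene Slc4a1 (2.89 ± 0.22, adjusted p = 8e-07), the blood group gene Rhd (2.46 ± 0.16) and the carbonic anhydrase gene Car2 (2.31 ± 0.19). The ammonium channel gene Rhag was higher by 3.21 ± 0.32. Cell cycle genes were higher beside them, with 7 of 25 G2/M genes (19 adjusted over the list alone; Ccna2 1.28 ± 0.20, Ccnb2 1.03 ± 0.16) and 7 of 31 G1/S genes (18 adjusted over the list alone). NK cell markers were lower, 7 of 10 (10 adjusted over the list alone; Klrb1c -1.37 ± 0.17), as were 5 of 14 T cell markers (10 adjusted over the list alone; Cd3g -1.14 ± 0.15). Jchain, which encodes the chain that joins IgM and IgA units, was lower (-5.31 ± 0.14, adjusted p = 1.39e-12), and so were 2 other plasma cell markers of the 8 tested, Derl3 (-1.11 ± 0.25) and Sdc1 (-0.57 ± 0.14), which makes 3 with Jchain (5 adjusted over the list alone). The largest rise was in BC018473 (4.83 ± 0.17, adjusted p = 3.52e-11). The Y-linked genes Eif2s3y (-4.77 ± 0.31) and Uty (-3.19 ± 0.23) were lower, so the sexes were not matched between the genotypes. Pan B cell markers gave no call (0 of 13 at adjusted p, 0 adjusted over the list alone, camera adjusted p = 0.309, fry adjusted p = 0.776). B-1 cell markers had none past the test for all genes and 4 of 8 lower adjusted over the list alone.

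The camera tests at 0 h gave 5.6e-33 for erythroid markers and 1.45e-20 for NK cell markers, and these calls held with an estimated correlation (adjusted p = 0.0294 each). They gave 1.34e-20 for G1/S and for G2/M, 5.76e-18 for T cell, 4.93e-13 for plasma cell and 2.52e-06 for B-1 cell markers. With an estimated correlation the adjusted p = 0.168, 0.182, 0.146, 0.0855 and 0.0715. NF-κB targets were lower as a list (median -0.14, adjusted p = 0.000203, and adjusted p = 0.497 with an estimated correlation) with 0 of 32 called, 0 adjusted over the list alone, 8 lower with the replicate as a block, and a fry adjusted p = 0.248. In all 180 genes rose and 98 fell. The count of 278 was 119 without wild type 0 h replicate 1, 158 without the TAK1-deleted 0 h replicate 1 and 837 with the replicate as a block.

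After 1 h of anti-IgM, NF-κB targets were lower in the TAK1-deleted samples. Of 32 tested, 10 fell and none rose (12 adjusted over the list alone): Tnfaip3 (-1.22 ± 0.16, adjusted p = 0.000149), the stress response gene Gadd45b (-1.20 ± 0.11), the adhesion molecule gene Icam1 (-1.14 ± 0.11) and Bcl2l1 (-1.09 ± 0.13, adjusted p = 7.48e-05) among them, with Nfkbia at -0.60 ± 0.10. The death receptor gene Fas (-2.04 ± 0.19) and the cytokine gene Il10 (-2.57 ± 0.23, adjusted p = 7.45e-06) were lower too. Of 28 immediate early genes 4 fell (4 adjusted over the list alone), Maff among them (-0.95 ± 0.17), and Egr1, Fos and Myc had no call (-0.07, -0.32 and -0.14). Of 12 anti-apoptotic genes 3 fell (3 adjusted over the list alone), of 15 surface markers 4 fell (5 adjusted over the list alone) and of 10 heat shock genes 3 fell (6 adjusted over the list alone; Bag3 -1.73 ± 0.15). In the same samples 9 of 9 erythroid markers, 10 of 25 G2/M genes and 11 of 31 G1/S genes were higher (9, 23 and 17 adjusted over the list alone). NK cell markers were lower in 8 of 10 cases and T cell markers in 10 of 14 (10 and 13 adjusted over the list alone).

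The adjusted p at 1 h was 1.34e-16 for NF-κB targets, 2.22e-05 for immediate early genes, 0.000146 for anti-apoptotic genes, 1.12e-06 for surface markers and 3.26e-08 for heat shock, and with an estimated correlation the adjusted p = 0.163, 0.548, 0.306, 0.318 and 0.146. It was 2.49e-17 for G2/M, 4.07e-18 for G1/S and 6.41e-21 for T cell markers, and with an estimated correlation the adjusted p = 0.201, 0.182 and 0.108. The erythroid (1.9e-22) and NK cell (2.91e-18) calls held with an estimated correlation (adjusted p = 0.0294 each). In all 248 genes rose and 264 fell. The count of 512 was 259 without wild type 1 h replicate 1, 280 and 325 without the TAK1-deleted 1 h replicates 1 and 2, and 1544 with the replicate as a block. When each array was centred on the median of the tested genes, 38.2% of the called genes were higher, against 48.4% in the values as deposited. The balance turned the other way with the replicate as a block (860 up and 684 down) and without wild type 1 h replicate 1 (152 and 107) or the TAK1-deleted 1 h replicate 2 (216 and 109).

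At 3 h NF-κB targets were again lower in the TAK1-deleted samples. Of 32 targets 12 fell and none rose (16 adjusted over the list alone), led by the cyclin D2 gene Ccnd2 (-1.87 ± 0.17, adjusted p = 1.3e-05), Bcl2l1 (-1.63 ± 0.13, adjusted p = 2.94e-06) and Tnfaip3 (-1.47 ± 0.16). Of 12 anti-apoptotic genes 5 fell (6 adjusted over the list alone; Pim1 -0.99 ± 0.15) and of 15 surface markers 7 fell (8 adjusted over the list alone; Slamf1 -1.63 ± 0.22, Icam1 -1.20 ± 0.11). Il10 (-2.14 ± 0.23) and Batf, a transcription factor gene needed for class switching (-1.34 ± 0.16), were lower. No immediate early gene was called by limma (0 of 28, 0 adjusted over the list alone). With the replicate as a block 3 were higher and 4 lower, and the list test gave an adjusted p of 0.481 by camera and 0.896 by fry, which became 0.00308 by camera without the TAK1-deleted 3 h replicate 1. The interferon list was lower (1 of 23 called, 1 adjusted over the list alone, camera adjusted p = 0.00446, and 0.632 with an estimated correlation), a call lost without wild type 3 h replicate 1 (0.125) or the TAK1-deleted 3 h replicate 2 (0.554). Erythroid markers stayed higher, 8 of 9 (9 adjusted over the list alone), while 8 of 10 NK cell, 4 of 14 T cell and 3 of 8 B-1 cell markers were lower (10, 11 and 5 adjusted over the list alone; Zbtb32 -1.39 ± 0.19).

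The adjusted p at 3 h was 3.65e-24 for NF-κB targets, 8.74e-10 for anti-apoptotic genes, 5.3e-13 for surface markers and 1.19e-15 for T cell markers. None of these held, with adjusted p = 0.0855, 0.115, 0.17 and 0.174 with an estimated correlation. The calls for erythroid (3.28e-22), NK cell (6.17e-18) and B-1 cell markers (1.27e-08) held with an estimated correlation (adjusted p = 0.0294, 0.0294 and 0.0398). The B-1 list shares Cd5 with the T cell list, whose markers were lower in the same samples and at 0 h. Whether the B-1 calls concern B-1 cells was not tested. In all 120 genes rose and 204 fell. The count of 324 was 134 and 154 without wild type 3 h replicates 1 and 2, 169 without the TAK1-deleted 3 h replicate 2, and 995 with the replicate as a block.

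At 6 h interferon-induced genes were lower. Of 23 interferon response genes 11 fell and none rose (17 adjusted over the list alone). Mx1 was lower (-1.05 ± 0.19, adjusted p = 0.0057), a call that was lost without wild type 6 h replicate 1 (adjusted p = 0.132) or the TAK1-deleted 6 h replicate 2 (adjusted p = 0.0986). Of 32 NF-κB targets 9 fell (17 lower and 1 higher adjusted over the list alone), with Ccnd2 at -1.62 ± 0.17, Tnfaip3 at -1.21 ± 0.16 and Bcl2l1 at -1.05 ± 0.13 (adjusted p = 0.000279). Il10 (-2.34 ± 0.23), the complement receptor gene Cr2 (-1.51 ± 0.15) and Batf (-1.13 ± 0.16) were lower, while Bmf, which encodes a cell death activator, was higher by 0.87 ± 0.11. Surface markers fell in 4 of 15 cases and anti-apoptotic genes in 4 of 12 (8 and 5 adjusted over the list alone). Erythroid markers were higher in 7 of 9 cases (9 adjusted over the list alone; Car1 2.24 ± 0.21), and 6 of 10 NK cell and 2 of 14 T cell markers were lower (10 and 6 adjusted over the list alone). The adjusted p was 2.7e-17 for the interferon list, 1.89e-13 for NF-κB targets, 1.3e-09 for surface markers, 4.08e-05 for anti-apoptotic genes and 1.11e-06 for T cell markers, and with an estimated correlation the adjusted p = 0.182, 0.182, 0.206, 0.258 and 0.383. The erythroid (8.8e-17) and NK cell (8.34e-14) calls held with an estimated correlation (adjusted p = 0.0457 and 0.045). In all 111 genes rose and 192 fell, and after quantile normalization of the arrays again 51.0% of the called genes were higher, against 36.6%. The count of 303 was 78 and 114 without wild type 6 h replicates 1 and 2, 131 and 85 without the TAK1-deleted 6 h replicates 1 and 2, and 1458 with the replicate as a block.

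**Figure D2:**
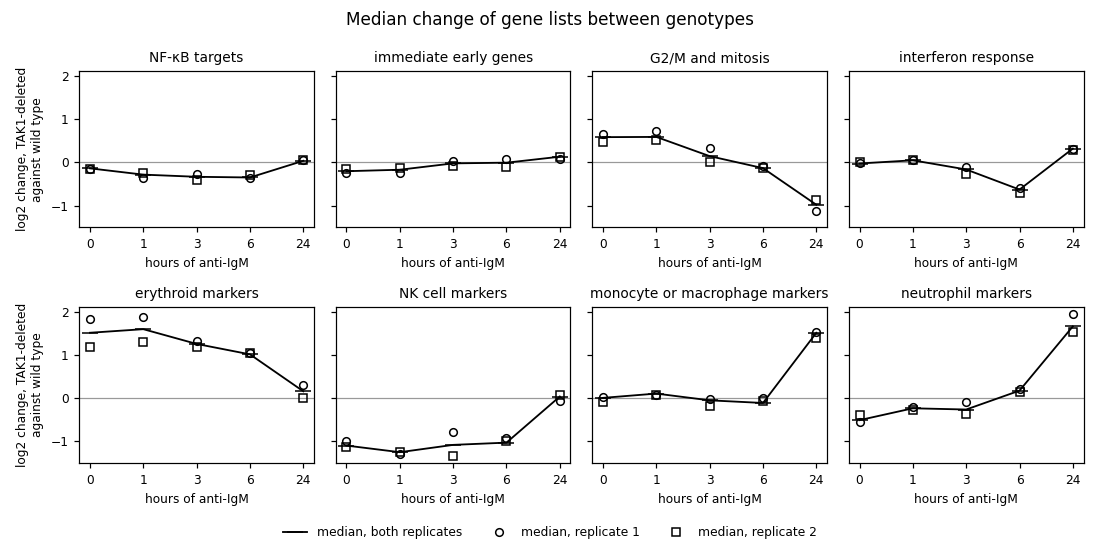
Median log2 change of 8 gene lists, TAK1-deleted against wild type, at each time of anti-IgM (time points drawn at even spacing); the line joins the median over the list's genes of the change in both replicates, circles and squares give the median in replicates 1 and 2. The NF-κB median went from -0.35 at 6 h to 0.04 at 24 h, the erythroid median from 1.51 at 0 h to 0.16 at 24 h, and the neutrophil median from -0.51 to 1.66.

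At 24 h the proliferation genes were lower in the TAK1-deleted samples. Of 25 G2/M genes 24 fell (25 adjusted over the list alone), with the mitotic motor gene Cenpe at -1.47 ± 0.23 (adjusted p = 0.000438) and Top2a at -1.32 ± 0.20. Of 31 G1/S genes 22 fell (27 adjusted over the list alone; Ccne2 -0.97 ± 0.16), and of 30 ribosome biogenesis genes 17 fell (27 adjusted over the list alone). Myc (-0.75 ± 0.15) and Bcl2l1 (-0.74 ± 0.13) were lower. Quiescence genes were higher, 11 of 22 (15 adjusted over the list alone), among them S1pr1 (1.42 ± 0.16), the transcription factor gene Klf2 (1.09 ± 0.17) and Txnip (0.92 ± 0.14). NF-κB targets went both ways, with 8 higher and 5 lower (12 and 6 adjusted over the list alone), a camera adjusted p of 0.281 and Ltb at 0.79 ± 0.12. Of 28 immediate early genes 6 were higher (6 adjusted over the list alone; Dusp5 1.09 ± 0.20), a list call (adjusted p = 0.0297) lost without the TAK1-deleted 24 h replicate 1 (adjusted p = 0.0712) or wild type 24 h replicate 2 (adjusted p = 0.087), with adjusted p = 0.74 with an estimated correlation.

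Myeloid transcripts were higher in the same samples. Of 17 monocyte or macrophage markers 15 rose (16 adjusted over the list alone), including the heme oxygenase gene Hmox1 (2.73 ± 0.18) and the scavenger receptor gene Marco (2.18 ± 0.15). Of 14 neutrophil markers 13 rose (14 adjusted over the list alone), with Ngp at 2.85 ± 0.20 and S100a8 at 2.48 ± 0.23. Rose here means higher than in wild type, where most of these markers fell from 0 h to 24 h. S100a8 read 9.36 and 9.7 at 0 h and 9.8 and 9.87 at 24 h in TAK1-deleted arrays. In wild type it read 9.83 and 10.25, then 7.33 and 7.39. C1qb fell in both genotypes, to 10.05 and 10.06 in TAK1-deleted arrays and 8.23 and 8.46 in wild type. Mmp8 went from 7.73 and 7.37 up to 8.31 and 8.2 in TAK1-deleted arrays. The largest single difference was in the aspartic protease gene Ctse (5.08 ± 0.19, adjusted p = 2.13e-10), which was already higher by 3.10 at 0 h and read 12.21 against 7.13 at 24 h, and Timd2 was lower (-2.60 ± 0.18). Dendritic cell markers rose in 4 of 9 cases (7 adjusted over the list alone; Siglech 2.07 ± 0.19) and T cell markers in 5 of 14 (7 adjusted over the list alone; Cd28 1.25 ± 0.23). Erythroid, NK cell and pan B cell markers had no list call (1 of 9, 1 of 10 and 3 of 13 higher, the same numbers adjusted over the list alone save 1 NK cell marker lower, adjusted p = 0.122, 0.895 and 0.0898), and with the replicate as a block the pan B cell list passed (adjusted p = 0.0401). The erythroid list passed without wild type 24 h replicate 2 (adjusted p = 0.00737). The calls for monocyte or macrophage (1.63e-21) and neutrophil markers (3.53e-22) held with an estimated correlation (adjusted p = 0.0294 each). The adjusted p was 1.56e-22 for G2/M, 6.03e-18 for G1/S, 3.35e-15 for ribosome biogenesis and 1.29e-10 for quiescence, with adjusted p = 0.17, 0.182, 0.212 and 0.318 with an estimated correlation. For dendritic and T cell markers it was 3.25e-05 and 8.65e-05, with adjusted p = 0.287 and 0.481 with an estimated correlation. In all 842 genes rose and 620 fell, while centring on the median of the tested genes gave 1161 and 1264 and leaving out wild type 24 h replicate 2 gave 521 and 651. The count of 1462 was 716 without wild type 24 h replicate 1, 769 and 699 without the TAK1-deleted 24 h replicates 1 and 2, and 3442 with the replicate as a block.

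Whether the response to anti-IgM differed between genotypes was tested as the change from 0 h in the TAK1-deleted samples minus that in wild type. Genes that responded less at 1 h included Il10 (-2.46 ± 0.33, adjusted p = 0.0048), the chaperone genes Hspa1l (-2.42 ± 0.22, adjusted p = 0.000126) and Bag3 (-1.60), and the lipase gene Lipg (-1.75 ± 0.24, adjusted p = 0.0048). Bcl2l1 responded less at 3 h (-1.72 ± 0.18, adjusted p = 0.00108). Coro2a differed by -1.68 ± 0.19 (adjusted p = 0.00116), reading 10.75 at 0 h and 11.25 at 3 h in wild type and 10.87 and 9.68 in the TAK1-deleted samples. At 1 h Bcl2l1 differed by -1.17 ± 0.18 (adjusted p = 0.0152), a call lost without any of 5 arrays: wild type 0 h replicate 1 (adjusted p = 0.108), wild type 1 h replicate 2 (0.0504), TAK1-deleted 0 h replicate 2 (0.101) and TAK1-deleted 1 h replicates 1 and 2 (0.0569 and 0.118). NF-κB targets as a list had a lower response at 1, 3 and 6 h (a negative difference, whichever way a gene moved): 3, 3 and 1 of 32 were lower (6, 9 and 6 adjusted over the list alone), with medians of -0.26, -0.33 and -0.22. The interferon list had a lower response at 6 h (median -0.63), where 0 of 23 genes were called by limma over all genes, 12 were lower adjusted over the list alone, 14 were lower with the replicate as a block, and fry gave an adjusted p of 0.0237. Immediate early genes gave no list call at 1 h (median -0.01, 0 of 28 by limma, 0 adjusted over the list alone, 1 lower with the block, adjusted p = 0.58 by camera and 0.932 by fry), and a call at adjusted p = 0.0279 without wild type 0 h replicate 1. The adjusted p for NF-κB targets was 1.25e-13, 4.93e-13 and 0.000133, and for the interferon list 1.34e-14. With an estimated correlation the adjusted p = 0.182, 0.194, 0.489 and 0.212.

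By 24 h the responses of cell cycle genes had parted. Of 25 G2/M genes 24 had a lower response in the TAK1-deleted samples, with a median change from 0 h of -0.26 there and 1.29 in wild type (24 adjusted over the list alone), among them Ccna2 (-2.25 ± 0.29, adjusted p = 0.000168) and Plk1 (-2.10 ± 0.32). Of 31 G1/S genes 25 had a lower response (29 adjusted over the list alone; Ccne2 -1.89 ± 0.23, Rrm2 -1.92 ± 0.28), as did 13 of 30 ribosome biogenesis genes (21 adjusted over the list alone; Gnl3 -0.97 ± 0.18) and Myc (-0.99 ± 0.22). Of 22 quiescence genes 10 fell less or rose more (12 adjusted over the list alone), including Tsc22d3 (1.45 ± 0.22) and S1pr1 (1.40 ± 0.23). T cell and NK cell markers moved the same way (medians 1.06 and 1.02, without a test), and whether such cells contributed to this list was not tested. The neutrophil genes S100a8 (2.99 ± 0.33) and Mmp8 (2.96 ± 0.28) differed upwards and the erythroid gene Rhag (-3.00) downwards, Mmp8 reading 5.95 in wild type and Rhag 5.49 and 5.28 in TAK1-deleted and wild type samples at 24 h, below the filter value of 7.45. Jchain was below that value in the TAK1-deleted samples at every time, so its difference (2.95) is the fall in wild type from 11.94 to 8.77. Every such difference includes the one at 0 h, where G2/M and G1/S genes were higher together with erythroid markers. The G2/M median was 0.58 at 0 h and -0.98 at 24 h between genotypes, against -1.54 for the response, and Ccne2 was 0.92 at 0 h and -0.97 at 24 h. The adjusted p was 3.26e-30 for G2/M, 1.3e-26 for G1/S, 1.21e-13 for ribosome biogenesis and 1.47e-11 for quiescence, and with an estimated correlation the adjusted p = 0.108, 0.108, 0.243 and 0.297.

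In all 13 genes differed in response at 1 h, all lower, 7 at 3 h, all lower, 34 at 6 h (11 higher and 23 lower) and 1037 at 24 h (553 and 484). With the replicate as a block the counts were 90 (12 higher and 78 lower), 233 (67 and 166), 772 (217 and 555) and 2633 (1323 and 1310). That all called genes were lower at 1 and 3 h thus holds only for the fit without the block. Fits of each contrast's arrays alone, with fewer degrees of freedom left, called 0 genes at 1 h and 0 at 3 h. At 1 h the count was 6 and 7 without wild type 0 h replicates 1 and 2, 8 without wild type 1 h replicate 1, 8 without the TAK1-deleted 0 h replicate 2, and 7 and 5 without the TAK1-deleted 1 h replicates 1 and 2. At 3 h it was 3 without wild type 0 h replicate 2, 3 and 4 without wild type 3 h replicates 1 and 2, 4 without the TAK1-deleted 0 h replicate 1, and 13 and 4 without the TAK1-deleted 3 h replicates 1 and 2. At 6 h it was 8 and 18 without wild type 0 h replicates 1 and 2, 1 and 4 without wild type 6 h replicates 1 and 2, 0 without the TAK1-deleted 0 h replicate 1, and 14 and 0 without the TAK1-deleted 6 h replicates 1 and 2. At 24 h it was 683 without the TAK1-deleted 24 h replicate 2. Quantile normalization again gave 12.5% higher among the genes called at 1 h and 23.1% at 3 h, centring gave 12.5% and 21.6%, and the values as deposited gave 0 at both times.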

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

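Chosen after the results were seen were the tests on the G2/M median at 6 h, the pan B cell median at 24 h, the NK cell to neutrophil ratio of the changes from 0 h and the ratios between 0 h and 24 h for monocyte or macrophage and for neutrophil markers.

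Erythroid and cell cycle transcripts were higher in the unstimulated TAK1-deleted samples, though the cell cycle list calls did not hold with an estimated correlation. More erythroid precursor cells are a candidate source: 21 other erythroid genes had a median of 0.81, all had a change above 0 in both replicates, 15 were called, and the abundant Car2 and Slc4a1 read 11.92 and 10.29 against 9.60 and 7.40, so that the CD43 depletion may have left more such cells in these samples, which is a hypothesis. A scale difference left in the deposited values is argued against as the whole cause, since the erythroid median after quantile normalization again was 0.956 of its value (1.44). The values had already been through RMA, and the repeat gave a median shift over all genes of only 0.0102. It therefore cannot tell of scaling at earlier steps. Whether those cells brought the cell cycle transcripts cannot be told apart from cycling B cells, since the G2/M median was -0.13 at 6 h, when erythroid genes were still higher but anti-IgM was also acting on the B cells. Sex, which was not matched between genotypes, and the TAK1-deleted genotype itself stay open and were not tested. That genotype joins the floxed alleles with the mb-1 deleter, and their effects cannot be told apart here.

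Cell cycle lists were lower in the TAK1-deleted samples at 24 h, in calls that did not hold with an estimated correlation. Whether a lower share of B cells contributed cannot be decided from the pan B cell markers, whose median was 0.128. All 13 fell in wild type by 24 h, so B cells that respond less could keep more of these transcripts and hide a lower share. A scale difference left in the deposited values is argued against, since the G2/M median after centring on the median of the tested genes was 1.02 times its value (-0.997). Centring gave a median shift over all genes of only -0.0182, so it cannot tell of scaling at earlier steps. Slower cell cycle entry, a loss of dividing cells and the sex of the mice stay open and were not tested here.

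Monocyte, macrophage and neutrophil markers were higher in the TAK1-deleted samples at 24 h. In wild type most of these markers fell from 0 h to 24 h, so a gain below means one relative to wild type. More monocytes or macrophages from the start are argued against by their median, which at 0 h was 0.00386 of that at 24 h. A scale difference left in the deposited values is argued against by a neutrophil median 0.987 of its value (1.64) after quantile normalization again. The repeat gave a median shift over all genes of only 0.0234, so it cannot tell of scaling at earlier steps. A lower share of B cells, which would raise the markers of every other cell type alike, cannot be told apart from a gain of myeloid cells: for the change from 0 h to 24 h the NK cell median was 0.524 of the neutrophil median (NK cell 1.02, T cell 1.06, monocyte or macrophage 1.48 and neutrophil 1.95, with overlapping quartiles), while erythroid markers went the other way (-1.49) and at 24 h alone the NK cell median was 0.0221 of the neutrophil median. The last 2 values carry the difference at 0 h, so neither decides on the share of B cells. Between genotypes the erythroid median was 1.51 at 0 h and 0.16 at 24 h, and the NK cell median -1.10 and 0.04. More neutrophils or their precursors from the start cannot be told apart from a later gain, since the neutrophil median at 0 h was -0.307 of that at 24 h but members went both ways, with Mpo and Elane higher at 0 h (1.81 and 1.40) and at 24 h (2.23 and 1.68), as were Ctsg (1.54 and 1.61) and Prtn3 (0.99 and 1.06), chosen after their values were seen. Myeloid cells that bear CD43 should be removed by the CD43 depletion, so any such source would be cells that escaped it; their longer survival or growth in culture, expression of these genes by B cells and sex could each contribute, and none of them was tested.

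The following values were picked because the change from 0 h differed between genotypes in the response test, with TAK1-deleted minus wild type given for each; counts of such genes were 13, 7, 34 and 1037 at 1, 3, 6 and 24 h. At 1 h they were Il10 (-2.46), Hspa1l (-2.42), Lipg (-1.75), Bag3 (-1.60), Bcl2l1 (-1.17), Icam1 (-0.90) and Gadd45b (-0.87), of which the calls of Bcl2l1, Icam1 and Gadd45b were lost on leaving out 1 array or another. At 3 h they were Il10 (-2.04), Bcl2l1 (-1.72), Coro2a (-1.68), Tnfaip3 (-1.33) and Icam1 (-0.96), and the calls of Il10, Tnfaip3 and Icam1 were lost in the same way. At 6 h they were Tlcd4 (-2.94), Reep6 (-2.49), Il10 (-2.23), Asns (-1.98), Bcl2l1 (-1.14), Slc7a5 (-0.83), Mir181b-2 (1.38), Retnlg (1.202), Rtn4rl1 (1.16) and Bmf (0.93). Every call at 6 h was lost on leaving out 1 array or another. Tlcd4, Reep6 and Retnlg differed more between genotypes at 0 h than at 6 h. In TAK1-deleted arrays Tlcd4 read 9.69 and 8.72 at 0 h and 5.94 and 5.89 at 6 h. In wild type it read 5.96 and 5.67, then 5.4 and 5.52. Reep6 read 10.77 and 10.17 against 8.38 and 8.11 in wild type at 0 h. At 6 h it read 10.97 and 10.3 against 11.11 and 10.68.

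At 24 h the cell cycle genes among them were Ccna2 (-2.25), Plk1 (-2.10), Hmmr (-2.02), Rrm2 (-1.92), Ccne2 (-1.89), Bub1 (-1.87), Chek1 (-1.74), Ccne1 (-1.67), Gtse1 (-1.07) and Rbl1 (-0.75). Metabolic and ribosome genes were Asns (-2.75), Slc16a1 (-1.85), Mthfd1 (-1.35), Rrs1 (-1.11), Slc7a5 (-1.05), Nhp2 (-1.05), Gnl3 (-0.97), Wdr43 (-0.93), Pfkm (-0.82), Hk2 (-0.68), Slc7a11 (1.43) and Slc16a3 (0.74). Genes of other cell types or of plasma cells were Rhag (-3.00), S100a8 (2.99), Mmp8 (2.96) and Jchain (2.95). Signalling and early genes were Dusp1 (2.19), Jun (1.83), Dusp5 (1.14), Map3k14 (0.81), Myc (-0.99) and Btg2 (0.93), and stress and death genes were Hspa1a (2.25), Hspd1 (-0.73), Hsp90aa1 (-0.54), Trp53inp1 (1.297), Fas (1.17), Bmf (0.99) and Bcl2l1 (-0.82). Immune genes were Il7r (2.10), Ccl5 (1.94), Tfrc (-1.81), Cd80 (1.62), Id2 (1.56), Tsc22d3 (1.45), S1pr1 (1.40), Bcl6 (1.32), Ifih1 (-1.13), Gcsam (1.04), H2-Oa (0.94), Tnfrsf9 (0.86), Ccl4 (0.82), H2-Ob (0.80) and Ltb (0.79). Tlcd4 (-3.46) and Cldn13 (-2.88) differed too. Both were higher in TAK1-deleted arrays at 0 h, and at 24 h both read below the filter value of 7.45 in both genotypes. The calls at 24 h of Bcl2l1, Ccl4, Cd80, Chek1, Dusp5, Gcsam, H2-Oa, Hk2, Hsp90aa1, Hspd1, Ifih1, Map3k14, Nhp2, Pfkm, Rbl1, Rrs1, Slc16a3 and Tnfrsf9 were lost on leaving out 1 array or another.

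List medians picked in the same way at 1 h were NF-κB targets (-0.264), surface markers (-0.11), chemokines and cytokines (-0.179), ribosome biogenesis (0.128), anti-apoptotic (-0.235), pro-apoptotic (-0.05) and amino acid genes (-0.039) and heat shock (-0.157). At 3 h they were NF-κB targets (-0.334), immediate early genes (0.324), surface markers (-0.336), quiescence (0.198), ribosome biogenesis (-0.199), G1/S (-0.308), G2/M (-0.413), anti-apoptotic genes (-0.312) and the interferon list (-0.231). At 6 h they were NF-κB targets (-0.223), immediate early genes (0.319), surface markers (-0.243), quiescence (0.316), ribosome biogenesis (-0.42), G1/S (-0.434), G2/M (-0.674), anti-apoptotic (-0.274), pro-apoptotic (0.167) and amino acid genes (-0.241) and the interferon list (-0.63). At 24 h they were NF-κB targets (0.248), immediate early genes (0.445), surface markers (0.305), chemokines and cytokines (0.178), quiescence (0.677), ribosome biogenesis (-0.695), G1/S (-1.024), G2/M (-1.539), pro-apoptotic genes (0.195), glycolysis (-0.345), amino acid genes (-0.465), antigen presentation (0.181) and p53 targets (0.337). Several of these list calls were lost on leaving out 1 array; below, each array named is the one left out and the value is the adjusted p without it. Without wild type 0 h replicate 1 they were ribosome biogenesis (0.132) and pro-apoptotic genes (0.0976) at 1 h, immediate early genes at 3 h (0.0587), and surface markers (0.114) and chemokines and cytokines (0.0756) at 24 h. Wild type 0 h replicate 2 ended chemokines and cytokines (0.0935) and amino acid genes (0.228) at 1 h, the interferon list at 3 h (0.06) and pro-apoptotic genes at 6 h (0.0549). TAK1-deleted 0 h replicate 1 ended chemokines and cytokines (0.0511) and amino acid genes (0.447) at 1 h, the interferon list at 3 h (0.0594), pro-apoptotic (0.154) and amino acid genes (0.0551) at 6 h and pro-apoptotic genes at 24 h (0.0997). TAK1-deleted 0 h replicate 2 ended ribosome biogenesis (0.218), pro-apoptotic genes (0.351) and heat shock (0.087) at 1 h, and surface markers (0.0684) and chemokines and cytokines (0.0565) at 24 h. At 1 h wild type replicate 1 ended chemokines and cytokines (0.133), anti-apoptotic (0.0523), pro-apoptotic (0.0567) and amino acid genes (0.393) and heat shock (0.172), and wild type replicate 2 ribosome biogenesis (0.35). TAK1-deleted replicate 1 ended ribosome biogenesis (0.598) and pro-apoptotic genes (0.115) at that time, and replicate 2 amino acid genes (0.34). At 3 h wild type replicate 1 (0.0883) and TAK1-deleted replicate 2 (0.33) ended the interferon list, and TAK1-deleted replicate 1 immediate early genes (0.407). At 24 h wild type replicate 1 ended chemokines and cytokines (0.0551) and pro-apoptotic genes (0.0548), wild type replicate 2 surface markers (0.066) and TAK1-deleted replicate 2 chemokines and cytokines (0.0631). With the replicate block alone, the calls at 1 h of pro-apoptotic genes, amino acid genes and heat shock were lost too. None of the list calls in this paragraph held with an estimated correlation, where the lowest adjusted p was 0.108. With the replicate block as well as an estimated correlation, a test chosen after the values were seen, NF-κB targets at 1 and 3 h (adjusted p = 0.0299 each) and quiescence at 24 h (adjusted p = 0.0333) passed.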

How the results depend on the processing

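The replicate numbers pair the samples (see the check of the pairing in the methods), and the replicate block raised the counts of called genes. The counts within genotypes became 5172 in wild type at 1 h, and 4340 and 5340 in TAK1-deleted samples at 1 and 24 h. Between genotypes they became 837, 1544, 995, 1458 and 3442 at 0, 1, 3, 6 and 24 h, and for the response 90, 233, 772 and 2633. Every gene called without the block was called with it, and Map3k7 passed at 1 h (0.299). Of 526 list and contrast pairs 159 had over 1.5 times as many members called with the block, and of 301 list calls 292 were kept and 10 gained. List calls lost within genotypes were pro-apoptotic genes in wild type at 1 h (adjusted p = 0.0322, with the block 0.0718), and in TAK1-deleted samples the unfolded protein response at 1 h (0.0476, with the block 0.0599) and p53 targets at 6 h (0.0407, with the block 0.0697). Between genotypes they were transitional or immature B cell markers at 0 and 24 h (0.049 and 0.0359, with the block 0.051 each) and marginal zone markers at 6 h (0.0252, with the block 0.0576), and for the response at 1 h pro-apoptotic genes (0.0264, with the block 0.0798), amino acid genes (0.0372, with the block 0.0556) and heat shock (0.0136, with the block 0.0567). List calls gained in wild type were quiescence (0.0383), G1 cyclins and CDK regulators (0.0352) and the interferon list (0.0359) at 3 h, G1 cyclins and CDK regulators at 6 h (0.0412) and the interferon list at 24 h (0.0415). Between genotypes they were antigen presentation at 0 h (0.0459), follicular markers at 1 h (0.0385), the interferon list (0.0393) and pan B cell markers (0.0401) at 24 h, and for the response the unfolded protein response at 1 h (0.0412). The block changed no other list call, and gene calls only by adding to them.

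Other settings moved counts by over 1.5 times as follows. The stricter filter gave 135 and 296 between genotypes at 0 and 1 h and 12 for the response at 3 h, and testing every probe set gave 8 and 18 for the response at 1 and 3 h. A change of at least 2-fold gave 781, 1762, 1761 and 1739 in wild type, 648, 1606, 1248 and 832 in TAK1-deleted samples, 107, 176, 95, 91 and 295 between genotypes and 538 for the response at 24 h; this and the next fall by construction. An adjusted p below 0.01 gave 1850 in wild type and 1464 in TAK1-deleted samples at 1 h, 2127 in the latter at 24 h, 161, 270, 159, 143 and 759 between genotypes and 6, 3, 10 and 557 for the response. The arrays of a contrast alone gave 1755 and 1534 within genotypes at 1 h, 150, 206 and 46 between genotypes at 0, 1 and 3 h, and 0, 0 and 19 by limma for the response at 1, 3 and 6 h (13, 7 and 34 in the fit of all arrays), where fewer degrees of freedom are left. Quantile normalization again gave 506, 903, 582, 668 and 2379 between genotypes, 32, 78, 280 and 1702 for the response, and Map3k7 past the test at 0 and 1 h (0.274 and 0.286). Centring gave 449, 885, 579, 695 and 2425, and 32, 88, 239 and 1743. Why both scalings raise the counts was not tested. List tests with an estimated correlation gave 18 calls and with the block besides 27. The kept share with genes chosen on replicate 2 was 83.5, 90.8, 76.8 and 49.3%, with genes at least 1.5-fold higher 56.1% at 24 h, and with genes at least 2-fold lower 102.5, 95.6 and 65.6% at 3, 6 and 24 h. No filter, the mean over probe sets and no intensity trend moved no count by over 1.5 times, and no setting reversed a called list or named gene. The balance of genes up and down is not firm: it turned under at least 1 setting in 12 of 17 contrasts, in 11 of them on leaving out 1 array. Centring turned it in wild type at 1 h (1856 up and 1812 down) and 3 h (3182 and 2858), in TAK1-deleted samples at 1 h (1578 and 1568), 3 h (3064 and 2712) and 24 h (2057 and 2064), and between genotypes at 24 h (1161 and 1264), and quantile normalization again between genotypes at 6 h (341 and 327). Map3k7 between genotypes, without a call, changed sign on leaving out 1 array at 3 and 24 h.

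Leaving out 1 array at a time gave 1853 to 2627, 4246 to 4615, 3947 to 4479 and 4167 to 4660 genes in wild type and 1496 to 1834, 4049 to 4281, 3188 to 3508 and 2069 to 2461 in TAK1-deleted samples. Between genotypes it gave 119 to 200, 259 to 392, 134 to 227, 78 to 131 and 699 to 1172, and for the response 5 to 17, 3 to 13, 0 to 36 and 683 to 957. Map3k7 ranged over 0.157 to 0.36, 0.164 to 0.433, -0.023 to 0.169, 0.008 to 0.102 and -0.038 to 0.248, list calls over 283 to 306, and the kept share over 89.5 to 92.1, 84.8 to 88.4, 64.7 to 73.7 and 52.5 to 54.7%. Over all arrays left out, 919 calls of named genes were lost and 7 were gained. The other 5842 combinations of gene, contrast and array did not change label, and they include genes without a call in either fit.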

Other observations

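The test on the chromosome of Map3k7 was chosen after the results were seen, in place of an earlier one on its 40 neighbours (0 called at all 5 times), which had too little power to decide.

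Metabolic, stress and antigen presentation genes moved in wild type as well. Of 16 p53 targets 8 rose and 2 fell in wild type at 1 h (8 and 2 adjusted over the list alone; Plk2 5.31 ± 0.20, Tnfrsf10b 2.16 ± 0.19; adjusted p = 0.00079, and adjusted p = 0.307 with an estimated correlation). Chemokines and cytokines rose in 6 of 12 cases at 1 h and fell in 1 (7 and 2 adjusted over the list alone; Il10 4.06; adjusted p = 0.00163, 0.497 with an estimated correlation). Of 16 glycolysis genes 10 rose and 1 fell at 24 h (10 and 1 adjusted over the list alone), with the lactate transporter gene Slc16a1 at 2.21 ± 0.21 and Pfkp at 1.79 ± 0.18 (adjusted p = 0.000925, 0.372 with an estimated correlation). Antigen presentation genes fell in 10 of 15 cases (10 adjusted over the list alone), with the class II transactivator gene Ciita at -2.15 ± 0.15 and H2-Ob at -1.96 ± 0.10 (adjusted p = 3.43e-05, 0.351 with an estimated correlation). Transitional or immature B cell markers fell in 4 of 5 cases at 24 h (adjusted p = 0.00985, 0.172 with an estimated correlation). Among the lists without a call in wild type at 24 h were the unfolded protein response (8 of 19 higher and 1 lower, 8 and 1 adjusted over the list alone, adjusted p = 0.123) and class switch and germinal centre genes (6 of 17 higher and 5 lower, 6 and 5 adjusted over the list alone, adjusted p = 0.914). So were G1 cyclins and CDK regulators (6 of 12 higher and 4 lower, adjusted p = 0.929), platelet or megakaryocyte markers (2 of 6 lower, adjusted p = 0.222) and the interferon list. G1 cyclins and CDK regulators had 3 higher and 9 lower at 3 h (3 and 9 adjusted over the list alone, adjusted p = 0.0614, and 0.0352 with the replicate as a block).

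Between genotypes, class switch and germinal centre genes were lower in TAK1-deleted samples at 1 h, 4 of 17 (4 adjusted over the list alone; Batf -0.93 ± 0.16, Id3 -0.78 ± 0.15; adjusted p = 0.000151, 0.284 with an estimated correlation), as were pro-apoptotic genes, 3 of 16 (3 adjusted over the list alone; adjusted p = 0.000906, 0.094 with an estimated correlation). Chemokines and cytokines were lower at 6 h, 2 of 12 (7 lower and 2 higher adjusted over the list alone; Ccl5 -0.80 ± 0.12; adjusted p = 0.000671, 0.449 with an estimated correlation). At 24 h cholesterol biosynthesis genes fell in 7 of 18 cases (11 adjusted over the list alone) and amino acid genes in 6 of 17 with 1 higher (10 and 1 adjusted over the list alone; Shmt1 -1.07 ± 0.15, Slc7a5 -0.63 ± 0.10, Slc7a11 1.60 ± 0.19). Glycolysis genes fell in 3 of 16 cases with 1 higher (6 and 1 adjusted over the list alone; Pfkp -1.10 ± 0.18, Hk2 -0.89 ± 0.12). For these 3 lists the adjusted p was 4.24e-05, 4.72e-05 and 0.0113, and with an estimated correlation the adjusted p = 0.384, 0.449 and 0.497. p53 targets were higher in 5 cases and lower in 1 (6 and 2 adjusted over the list alone; Trp53inp1 1.17 ± 0.11, Btg2 0.81 ± 0.08; adjusted p = 0.0174, 0.475 with an estimated correlation), and genes of the unfolded protein response were lower in 2 of 19 (2 adjusted over the list alone; adjusted p = 0.00751, 0.497 with an estimated correlation). Platelet or megakaryocyte markers were higher in 3 of 6 (3 adjusted over the list alone; adjusted p = 0.00927, 0.194 with an estimated correlation), a call lost without wild type 24 h replicate 1 (adjusted p = 0.07). Antigen presentation genes were higher in 2 of 15 (adjusted p = 0.0427, 0.632 with an estimated correlation), a call lost without wild type 24 h replicate 1 (0.0535) or 2 (0.0716) or the TAK1-deleted 24 h replicate 1 (0.0786). Transitional or immature B cell markers were higher in 1 of 5 at 3 h (2 adjusted over the list alone; adjusted p = 0.00212, 0.108 with an estimated correlation).

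A total of 26 genes were called the same way between genotypes at all 5 times, 16 higher and 10 lower. Sequence carried along with the Map3k7 allele is argued against as a common source of these by where they lie. The Y-linked Eif2s3y and Uty among them could not have this source in any case. On the chromosome of Map3k7 lay 767 of the 11968 tested genes, and a share of 0.0385 of these genes, 1 of 26 (places taken from the GRCm38.p6 annotation). For that 1 gene, and for 6 of the 40 tested neighbours of Map3k7 that were called at some time, it stays open. The Y-linked gene Eif2s3y read 4.63 to 4.89 in the TAK1-deleted samples and 8.32 to 9.82 in wild type, and Xist 12.51 to 13.08 and 11.85 to 12.38. The label of mixed sex is thus not borne out for the TAK1-deleted arrays, where Eif2s3y, Uty and Kdm5d stayed below the filter value of 7.45. Wild type arrays carried both Y-linked transcripts and Xist.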
